A study of Mus musculus with 5 samples.

How the data were processed

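The series holds 5 samples of MEL cells, a mouse erythroleukemia line. In 3 samples the RNA bound by PABPC1, the main cytoplasmic poly(A) binding protein, was recovered by CLIP-seq. In this assay ultraviolet light links proteins to the RNA they touch, the protein is precipitated with an antibody and the attached RNA fragments are sequenced. Per the labels, cells were irradiated at 400 mJ/cm2, the lysate was treated with RNase for 10 min, and PABPC1-RNA complexes were taken from a membrane. The other 2 samples are mRNA-seq of the same line. A second cell line, NIH-3T3, is named in the growth protocol and was not used here.

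The deposited CLIP-seq data used here were 1 peak list and 1 list of deletion sites, each named in the labels for all 3 CLIP-seq samples, so the replicates were pooled by the authors and could not be separated. The peak list gives each peak a strand and a whole-number score, the authors' own value, whose meaning is not given in the sources used here. The score was read as the peak's height in tags, because the tag coverage of 99.8% of the 10137 deletion sites inside a peak did not exceed that peak's score. Peak height was used to describe, rank and filter peaks within that list and, summed over a gene's exonic peaks, as the CLIP signal set beside RPKM. The second list gives single bases with the authors' count of tags that carry a deletion there and, per the labels' file terms, a second number, taken here as the tags covering the base. Deletions of this kind arise when reverse transcriptase passes the cross-linked base, so they place the contact more closely than a peak does. The threshold used for either list is not given in the sources used here. The name of the peak list carries the term gencode and that of the deletion list does not. Whether peaks were called on annotated genes alone is not given. The mRNA-seq file holds the authors' RPKM (reads scaled by gene length and by library size), 1 value a gene for both mRNA-seq samples together, and genes at 0 are not listed. The submitters' processing notes name cutadapt 1.4.2, Novoalign 3.02.02, TopHat2 2.0.12 and HTSeq 0.6.0 and the genome build mm10, without the role of each.

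The RPKM were turned back into reads as a check of the unit. Among the 4946 listed genes whose versioned identifier matched the annotation used, 100% of the 3560 genes under 200 reads gave a whole number within 0.01 when 1 read in a gene of 1 kb was worth an RPKM of 0.0284. That step corresponds to 35251228 reads in 1 pooled count, and 766 genes were worth 1 read. No value per mRNA-seq replicate could be had, so the planned comparison of the mRNA-seq replicates was not made. The planned designs assumed a height and a deletion count for each pooled list, which is what the files held.

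Sites were placed on GENCODE mouse release M21, basic transcripts, on mm10, by strand, with 1-based coordinates. Where transcripts disagreed, the order was 3' UTR, 5' UTR, coding sequence (CDS), non-coding exon, intron. A peak was placed by its midpoint. Of the RPKM identifiers, 98.4% were found in the annotation and 290 were not. A peak's genes were those with an exon on its strand under the midpoint. Expected shares of regions put each site uniformly on the collapsed exons of its own gene. Background positions for bases, hexamers, poly(A) signals and distances were drawn from the same region of the same transcript. There were 100 draws a deletion site, 20 a peak for poly(A) signals and distances, 10 a site for hexamers, and fewer in some alternatives. For the overlap of deletion sites with peaks, positions were drawn from the exons of the whole transcript. All hexamers were counted in windows of 20 nt either side of the site. A hexamer was ranked if it lay in at least 50 windows of the sites or, as a mean over draws, of the drawn positions. Poly(A) signals were AATAAA and ATTAAA within 50 nt. Distances ran along the spliced 3' UTR to the nearest annotated transcript end downstream. Sequences came from annotated transcripts, so the sequence of introns and of sites outside genes was not analysed here.

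CLIP signal per gene was the summed height of its exonic peaks. Ratios to abundance were log2((summed height + 1)/(RPKM + 1)), a scale on which the pseudocount of 1 understates the ratio of low genes. RPKM is divided by gene length and summed height is not, so the ratio may also vary with gene length. Each of 17 gene lists was fixed before the data were examined: erythroid genes, cytosolic ribosomal proteins, translation factors, poly(A) tail binding, deadenylation and decay, cleavage and polyadenylation, replication-dependent histones, mitochondrially encoded genes, long non-coding RNAs, the nuclear-encoded respiratory chain, hnRNP and SR proteins, the proteasome, glycolysis, chaperones, immediate-early and AU-rich mRNAs, the cell cycle, fibroblast markers and markers of other blood cells. A list's median over genes with RPKM of at least 1 was placed among 10000 random lists of the same size matched on RPKM in 20 bins, and lists outside the 2.5th to 97.5th percentile were called apart from their matches. The share of a list's genes with a peak was placed in the same way.

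The design, the tests, the gene lists and the alternatives were fixed before the data were examined, except where stated. The genes named were, by a fixed rule, the 8 with the tallest peak, the 8 with the largest and the 8 with the smallest ratio of height to RPKM among genes with RPKM of at least 10 and a peak, the 5 with the highest RPKM and no peak, the 8 with the most deletion sites, the 8 with the tallest 5' UTR peak, a set of globin and reference genes with Pabpc1, and the 3 members of each list with the highest RPKM. 1 gene that the rule takes is not reported here. The hexamers named were the 10 highest, the 5 lowest and 5 fixed ones, with TTTTTT added after the data were seen. Single deletion sites with the most deletions were chosen after their values were seen, as were M21 and its basic set.

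With pooled lists there is no replicate error and no p-value. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios carry 95% intervals from 1000 resamplings of genes, since sites of a gene are not independent. Intervals of shares weighted to coverage come from 1000 resamplings of single sites. These and the binomial intervals treat sites as independent, so they may be too narrow. These intervals cover counting and the choice of genes only. Tags amplified by PCR are not independent molecules, and no interval covers differences between cultures.

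Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. The steps were tested on simulated data. With positions drawn at random in place of the 9620 deletion sites used for hexamers, the log2 ratio of AATAAA was 0.01; with 1569 of them moved onto AATAAA it was 1.93 against 1.94 planted. The 3' UTR ratio of 9723 uniform positions was 0.998, and 1.30 against 1.31 when 3' UTR bases were weighted 2 to 1. The ratio near transcript ends was 1.02 and that of poly(A) signals 1.02 for 8753 drawn positions. Of 100 simulated lists of 30 genes among 12331, 1 was called with no shift, 81 with a log2 shift of 1 and 100 with a shift of 2.

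Alternatives tried were stricter peak heights and deletion counts, the region order, the placement of peaks, the background, window sizes, single regions, sites away from ends, the longest 3' UTR, RPKM filters, tallest peak or number of peaks in place of summed height, the pseudocount, and matching on RPKM times exon length. Added after the data were seen were the comprehensive annotation, joining sites within 10 nt, leaving out sites deleted in at least 50% of tags, hexamers more than 100 nt from an annotated end, intronic peaks, protein-coding genes alone, and the correlation with RPKM times exon length.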

Results

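PABPC1 contacts on RNA were mapped in MEL cells by CLIP-seq in 3 samples, and mRNA abundance was measured by mRNA-seq in 2 samples of the same line. The CLIP-seq samples were represented by 1 pooled list of 90337 peaks and 1 pooled list of 11907 deletion sites, and the mRNA-seq samples by 1 RPKM value a gene, so no value below has a replicate error. Peak height ranged from 2 to 10814 tags with a median of 9, and its quartiles were 5 and 23 tags. Median peak width was 66 nt. The heights summed to 3414820 tags, of which the 100 tallest peaks held 7.60%. Exonic peaks fell in 12360 genes, with a median of 4 peaks a gene, and 2659 genes held 10 or more. Deletion sites carried 3 to 2205 deletions with a median of 12, at a median coverage of 124 tags, and the median site was deleted in 12.8% of its tags. The 262597 deletions fell at bases that often adjoined: 47.8% of sites had a neighbour within 1 nt, and joining sites within 10 nt left 8206 runs. The RPKM values had a median of 6.62 and rested on 35251228 reads.

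PABPC1 is known for binding the poly(A) tail, and the study asked whether it also binds sequences encoded in the genome, within the body of mRNAs. Deletion sites lay mostly in 3' UTRs. Of the 11907 sites, 73.5% (95% interval 72.7 to 74.3) fell in a 3' UTR, 7.53% in CDS and 0.613% in a 5' UTR, while 4.38% were intronic, 2.57% lay in non-coding exons and 11.4% outside annotated genes. Peaks were spread more evenly over mRNAs, with 45.9% (45.6 to 46.2) in 3' UTRs, 35.0% in CDS, 2.16% in 5' UTRs, 13.5% in introns, 2.88% in non-coding exons and 0.486% outside genes. The shares outside genes are not compared between the lists, since peaks may have been called on annotated genes alone.

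Relative to a uniform placement on the exons of the same genes, 3' UTRs held 2.04 times as many deletion sites (95% interval 1.99 to 2.08; 90.0% of 9723 sites in mRNA exons against 44.2%). The CDS held 0.205 times as many (0.188 to 0.221; 9.23% against 45.0%) and 5' UTRs 0.0694 times as many (0.0434 to 0.104; 0.751% against 10.8%). Among 75074 peaks in the mRNA exons of 10687 genes the same order was shallower: 1.23 (1.22 to 1.25) for 3' UTRs, 0.907 (0.895 to 0.917) for CDS and 0.300 (0.286 to 0.315) for 5' UTRs. The contrast was steeper for peaks of at least 74 tags, with 1.91 for 3' UTRs, 0.339 for CDS and 0.0937 for 5' UTRs. Pabpc1 alone held 11 of the 73 deletion sites in 5' UTRs.

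**Figure D1:**
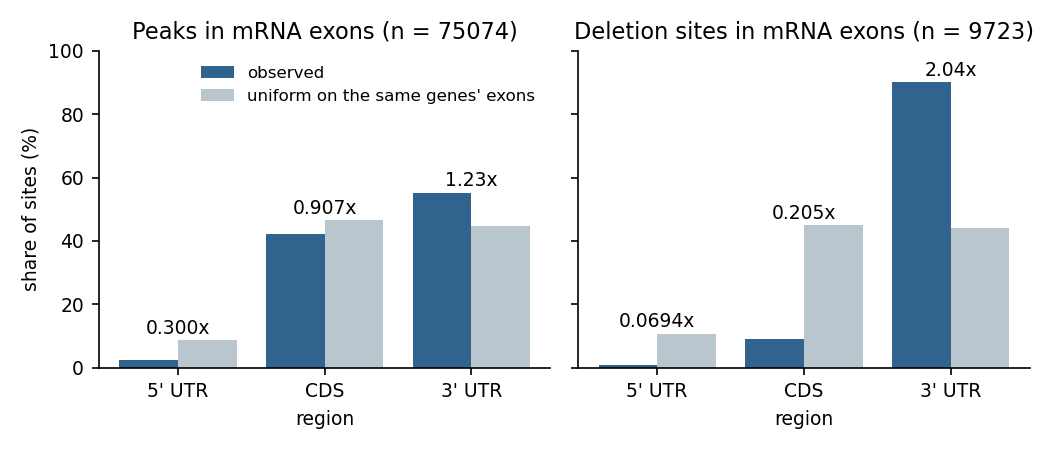
Share of peaks (left) and deletion sites (right) in 5' UTR, CDS and 3' UTR, as a percent of those in mRNA exons, with observed shares in blue and shares for uniform placement on the same genes' exons in grey. The numbers above the bars are observed over uniform shares, 1.23 for peaks and 2.04 for deletion sites in 3' UTRs.

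Most deletion sites lay inside a peak, while most peaks held no deletion site. Of all deletion sites, 10137 of 11907 lay in a peak on the same strand, 85.1% (95% interval 84.5 to 85.8). Among exonic sites the share was 96.2%, against 42.8% for positions drawn from the exons of the same genes, a ratio of 2.25 (2.20 to 2.31). Both lists come from the same tags, so the overlap is not an independent check of position.

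At the deleted base itself A and T were in excess and C and G were scarce. Among 9620 exonic sites with a full window, 48.6% were T against 29.3% at positions drawn from the same regions, a ratio of 1.66 (95% interval 1.63 to 1.69). A made up 44.2% against 26.4%, a ratio of 1.67 (1.63 to 1.71). C and G together made up 7.18% against 44.3%, a ratio of 0.162 (0.148 to 0.177). Downstream of the deletion the sequence was rich in A, which reached 50.5% of sites 4 nt 3' of the deleted base.

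**Figure D2:**
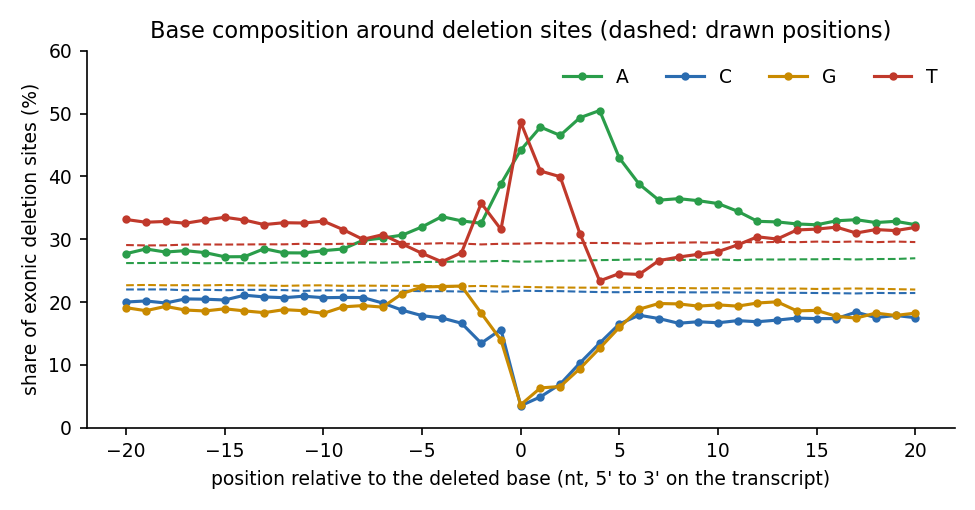
Percent of exonic deletion sites with A, C, G or T at each position from 20 nt upstream to 20 nt downstream of the deleted base, in transcript direction, with dashed lines for positions drawn from the same regions. A rises to 50.5% at 4 nt downstream, and T stands at 48.6% at the deleted base.

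Hexamers made of A and T marked the deletion sites. ATATAA had the highest ratio of all hexamers, with a log2 ratio of 3.06 (95% interval 2.92 to 3.21), and lay within 20 nt of 13.3% of sites against 1.60% of drawn positions. AATAAA, the main poly(A) signal, lay near 29.2% of sites against 5.43%, a log2 ratio of 2.42 (2.34 to 2.51). AAAAAA, encoded in the genome but of the same sequence as the tail, had a log2 ratio of 1.99 (1.86 to 2.10), with 11.8% of sites against 2.96%. The other leading hexamers were GATATA at 2.76, AATATA at 2.68, CATATA at 2.52, AAATAA at 2.47, AAAATA at 2.27, ATATAT at 2.16, ATAATA at 2.14 and ATAAAC at 2.14. The second poly(A) signal, ATTAAA, reached 1.05 (0.85 to 1.22). TTTTTT had a log2 ratio of 0.01, GTTTGT 0.10 and TGTTTG 0.12, each with an interval that included 0. Against positions from any exon of the same gene they stood higher, TTTTTT at 0.80 (0.61 to 0.98), GTTTGT at 0.68 (0.39 to 0.95) and TGTTTG at 0.57 (0.32 to 0.80). The lowest hexamers were rich in G: GGCTGG at -2.38, GCAGGG at -2.41, GGGGCC at -2.46, GGATGG at -2.62 and GGGGGC at -2.83. Each lay in only 10 to 34 windows of the sites, and was ranked through its count in drawn windows.

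Coding sequence carried the same hexamers. In the 897 CDS sites ATATAA had a log2 ratio of 4.28 (95% interval 4.01 to 4.57), with 21.6% of sites against 1.11%, and AATAAA a ratio of 2.61 (2.01 to 3.12). AAAAAA stood at 2.40 there. In 5' UTRs, with 72 sites, AATAAA had a log2 ratio of 2.32, but its interval reached 0. With windows of 50 nt the ratio of AATAAA over all sites was 1.54, while TTTTTT rose above background at 0.40 (0.28 to 0.51).

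Peaks shared AATAAA, AAATAA and ATAATA with the 10 leading hexamers of deletion sites, at lower ratios, while ATATAA was not among their 10 leading ones. Around the midpoints of 76942 exonic peaks AATAAA had a log2 ratio of 1.37 (95% interval 1.33 to 1.41), with 6.62% of windows against 2.56%. AAAAAA had 0.97 (0.92 to 1.02) and ATTAAA 0.72 (0.65 to 0.78). ATAACG led the peaks at 1.39 with only 266 windows, followed after AATAAA by ATAATC at 1.30, ATAAAG at 1.28, AAATAA at 1.28, TAATAA, GATAAT, AGATAA and CAATAA at 1.27 each, and ATAATA at 1.25. TTTTTT was below its background at -0.30 (-0.37 to -0.23), though with windows of 50 nt it stood above it at 0.17, and its interval included 0 for peaks of at least 74 tags (0.10) and against positions from any exon of the same gene (-0.04). GTTTGT (-0.002) and TGTTTG (-0.04) had intervals that included 0. The lowest were GGGGCG at -1.38, CGGCGG at -1.40, GGCGGG at -1.48, CGGGCG at -1.53 and GGGCGG at -1.74. In CDS peaks alone AATAAA had a log2 ratio of 1.54, and with windows of 50 nt around all midpoints 0.90.

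**Figure D3:**
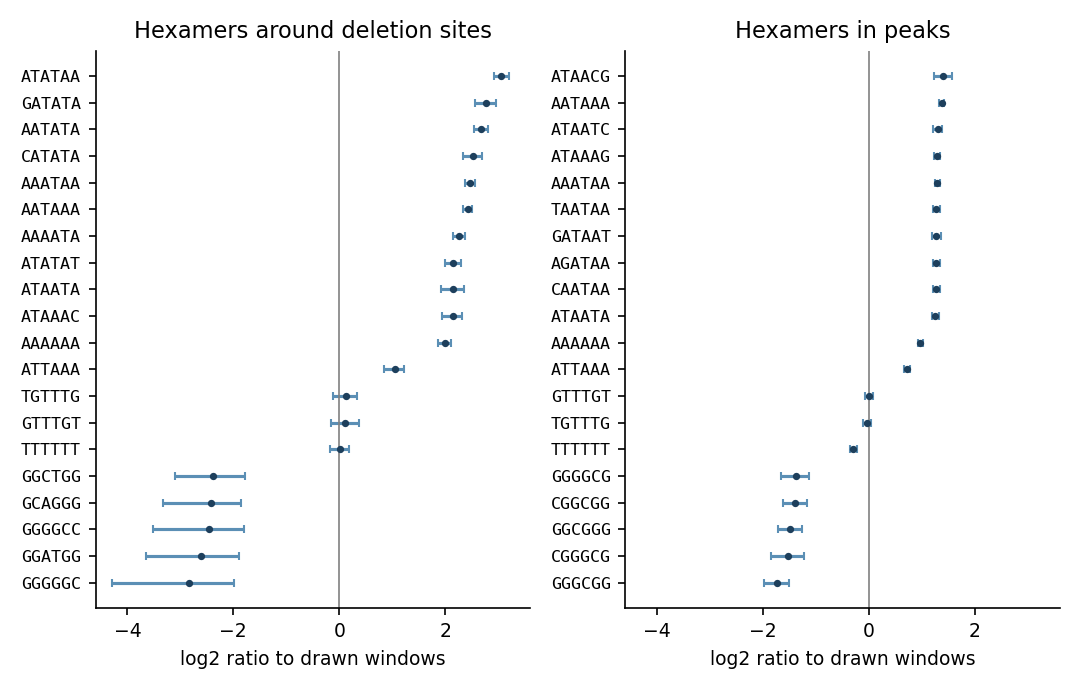
Log2 ratio of the share of windows holding each named hexamer to the share in windows drawn from the same regions, around deletion sites (left) and peak midpoints (right). Points are ratios and bars 95% intervals from resampling genes; ATATAA at 3.06 and AATAAA at 2.42 stand far above 0 at deletion sites, while TTTTTT stands at 0.01.

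In 3' UTRs the deletions gathered near poly(A) signals and near the transcript end. A poly(A) signal lay within 50 nt of 4771 of 8753 deletion sites, 54.5% against 21.2% for positions in the same 3' UTRs, a ratio of 2.57 (95% interval 2.47 to 2.66). For sites more than 50 nt from an annotated end the shares were 36.9% and 15.7%. For 3' UTR peaks they were 25.6% of 41466 and 15.6%, a ratio of 1.64 (1.61 to 1.66). The median distance from a deletion site to the next annotated end was 124 nt, against 391.9 nt for drawn positions, and 46.8% of sites lay within 100 nt against 19.9%, a ratio of 2.35 (2.26 to 2.45). The bin from 20 to 30 nt before the end held 1164 sites, 13.3% against 2.00%. Peaks lay farther away, at a median of 544 nt against 655 nt, with 19.6% within 100 nt against 12.0%, a ratio of 1.63 (1.61 to 1.66). The other deletion sites lay farther from an annotated end.

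**Figure D4:**
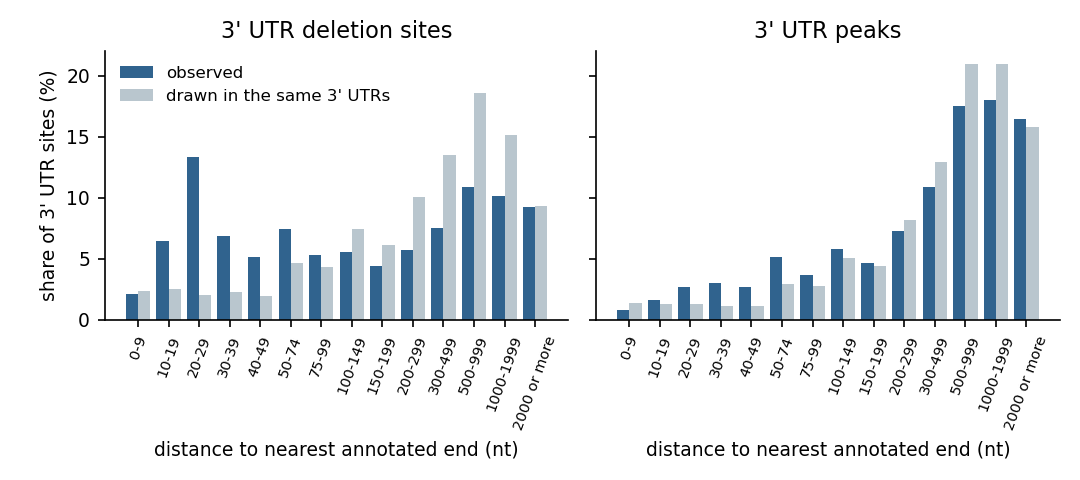
Percent of 3' UTR deletion sites (left) and 3' UTR peaks (right) by distance in nt to the nearest annotated transcript end downstream, observed in blue and for positions drawn in the same 3' UTRs in grey. Deletion sites peak at 20 to 30 nt with 13.3% against 2.00%.

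Single transcripts show these positions. The tallest peak, at 10814 tags, lay in Rpl4 (chromosome 9, 64178226 to 64178594, plus strand, midpoint in the CDS), which encodes a protein of the large ribosomal subunit. Gm26924, a non-coding gene on chromosome 17 in a region that resembles ribosomal RNA, followed with 8068 tags (39847382 to 39848777). The 3' UTR of Psat1, an enzyme of serine synthesis, held a peak of 7440 (chromosome 19, 15904954 to 15906153, minus strand). Other tall peaks lay in Ndufa13 of respiratory complex I (6446), the splicing regulator Hnrnpa2b1 (5762), the initiation factor Eif3g (5327) and the chaperone Canx (5126). The peaks of Psat1, Hnrnpa2b1, Eif3g and Canx had their midpoint in a 3' UTR.

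Deletion sites were most numerous in Gm26924 with 27, followed by Serbp1 and the cyclin gene Ccnd2 with 25 each, Actb and the desaturase gene Scd2 with 21 each, the beta-globin gene Hbb-bs with 19, Arpc2 with 18 and Hdgf with 17. Some single sites, chosen after their values were seen, were deleted in a large share of tags. In the 3' UTR of Hbb-bs, position 103826585 on chromosome 7, 51 nt before the end, was deleted in 836 of 1064 tags, 78.6%, beside none of ATATAA, AATAAA and AAAAAA. The adjoining position 103826584 was deleted in 66.7% of its tags, while the median 3' UTR site was deleted in 10.4%. A difference of this line's genome, or of another globin copy, from the reference may contribute at these Hbb-bs positions. It was not tested there, so they are not clear cases of contact. Psma1, a proteasome subunit gene, had 741 deletions in 2397 tags at position 114264747 on chromosome 7, beside an ATATAA and 141 nt before the end. Actb had 644 in 2329 tags at position 142903727 on chromosome 5, beside an AAAAAA. Taking 1 site a gene, the 5 coding sites with the most deletions lay in Mcts1 (239 in 611 tags; chromosome X, 38613294), Eif5a (198 in 582; chromosome 11, 69917442), Eif3g (187 in 4981; chromosome 9, 20894427), Luc7l3 (141 in 349; chromosome 11, 94295974) and Eif1ax (136 in 495; chromosome X, 159377520). Those of Mcts1 and Luc7l3 lay beside an ATATAA, and the other 3 beside none of ATATAA, AATAAA and AAAAAA. The most deletions, 2205 in 5822 tags, lay in the processed pseudogene Gm6440 (chromosome 16, 17137334), at a site outside every peak and also beside none of those hexamers. The strongest sites of Rpl4, Psat1, Hnrnpa2b1, Canx, Scd2 and Hdgf were likewise beside none of those hexamers, but each lay inside its gene's tallest peak.

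PABPC1's own mRNA was bound in its 5' UTR. Of 1955 peaks in 5' UTRs, the peak of Pabpc1 was the second tallest at 2221 tags (chromosome 15, 36608310 to 36608978, minus strand). The gene held 13 peaks, 11 of them in CDS and 1 in the 3' UTR at 762 tags, and 16 deletion sites, of which 11 lay in the 5' UTR, 2 in CDS and 3 in the 3' UTR. The 467 nt of 5' UTR under the tall peak held 11 starts of AAAAAA, against 0 under the other 7 tallest. Its share of A was 20.6%, beside 20.3% over all 5' UTRs with a peak.

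The other tall 5' UTR peaks lay mostly on mRNAs of the ribosome. Rplp1, a stalk protein of the ribosome, had the tallest at 3929 tags (chromosome 9, 61914330 to 61914562). Gnb2l1, whose product RACK1 sits on the small ribosomal subunit, followed Pabpc1 with 878, then Rps20 with 828, Rplp2 with 693, and, among the lower ones, Tpt1 with 560 and the metallothionein gene Mt1 with 533. Counting peaks of at least 9 tags left 860 peaks in 5' UTRs, and peaks of at least 74 tags left 86, with Pabpc1 at rank 2 in both.

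Abundant mRNAs carried more CLIP tags. Across 10721 genes with RPKM of at least 1 and an exonic peak, summed height and RPKM had a Spearman's rho of 0.615 (95% interval 0.602 to 0.628) and a Pearson's r of 0.593 on log2 values. Genes are not independent replicates, so no p-value is given. The relation was weaker for the number of peaks, at a rho of 0.283. Pabpc1 stood at RPKM 1143 with a summed height of 4385, and Actb at 785 with 4725. The nuclear RNA Malat1 had RPKM 206 and a summed height of 438 in 15 peaks.

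Most expressed genes held a peak. Among genes with RPKM of at least 1, 10721 of 12331 did, 86.9% (95% interval 86.3 to 87.5). The share was 63.5% at RPKM 1 to 5, 90.8% at 5 to 20, 95.5% at 20 to 100 and 92.7% above 100. Protein-coding genes reached 96.6%, and 1124 of 1125 of them above RPKM 100 held a peak. Processed pseudogenes held one in 453 of 1017 cases, 44.5%, although they took up 20.0% of the summed RPKM. Shares were lower for genes of small RNAs, 17.8% for snoRNA genes and 7.10% for miRNA genes. Counting peaks of at least 74 tags alone left 46.8% of the 12331 genes with a peak.

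Height relative to RPKM varied widely between genes. Among genes with a peak and RPKM of at least 10, the beta-globin gene Hbb-bs had the largest log2 ratio at 7.82, from a summed height of 4664 at RPKM 19.6. It was followed by Impad1 at 6.87, the surface protein gene Cd47 at 6.79, Tmem258 at 6.64, Strbp at 6.64, the presenilin gene Psen2 at 6.64, Asxl2 at 6.60 and the deadenylase gene Cnot6l at 6.58. The tallest peak of all 8 lay in the 3' UTR. Summed height is not divided by gene length and RPKM is, so a large ratio may partly come from a long transcript with many peaks. Cnot6l held 39 peaks, Strbp 33, Asxl2 30, Cd47 26 and Impad1 11, against a median of 4 a gene. Tmem258 and Psen2 held 3 each and Hbb-bs 2. The 8 smallest ratios belonged to processed pseudogenes: Gm13456 at -9.13, Rpl18-ps2 at -8.45, Gm14303 at -7.89, Gm6548 at -7.42, Gm6180 at -7.39, Rps26-ps1 at -7.35, Gm4149 at -6.45 and Rps3a2 at -6.39. Of the 5 most abundant genes without a peak, Gm23935 is a miRNA gene (RPKM 10519), and Gm8730, Rpl38-ps2, Gm4617 and Rpl39-ps are processed pseudogenes.

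Genes with near-identical copies have uncertain values in both files, since the handling of shared reads is not given in the sources used here. The glycolytic gene Gapdh, which has many processed pseudogenes, stood at RPKM 7.87 with a summed height of 31, and Tpt1 at RPKM 8.34. Among globins, Hba-a1 had RPKM 38.3 and a summed height of 339, Hbb-bt RPKM 5.61 and 1911 (log2 ratio 8.18, above that of Hbb-bs), and Hba-a2, absent from the RPKM list, a summed height of 11. Hbb-b1 and Hbb-b2 were not found in the annotation used.

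Of 15 gene lists that could be tested, 4 stood above and 1 below their matched random lists by height over RPKM. Lists drawn like their matches would give 0.75. The matches also held pseudogenes and genes of small RNAs, which less often held a peak, and were not matched on length. So 0.75 is not the chance count for lists of mostly protein-coding genes. In all settings, protein-coding genes alone among them, erythroid genes stayed at or above percentile 98.7. Genes of hnRNP and SR proteins stayed at or above 98.4. Erythroid genes, the lineage program of these cells, had a median log2 height over RPKM of 3.11 against 2.02 for matched lists, at the 99.98th percentile, and all 29 held a peak. The transcription factor Klf1 (-0.24), the oncogene Myb (0.29) and the carbonic anhydrase gene Car2 (2.20), its 3 most abundant members, lay on both sides of the matched median. Genes of hnRNP and SR proteins, which control splicing, stood at 2.86 against 1.82 (30 genes, 99.97th percentile), with Hnrnpa2b1 at 3.37, Hnrnpab at 3.42 and Hnrnpm at 2.19. Genes of poly(A) tail binding, deadenylation and decay stood at 3.44 against 2.60 (39 genes, 99.82nd percentile), with the release factor gene Gspt1 at 2.94, the CCR4-NOT scaffold gene Cnot1 at 2.48 and Pabpc1 itself lower at 1.94. With the tallest peak in place of summed height that list was at 91.4, inside the range of its matches.

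Cytosolic ribosomal protein genes stood below their matches. Their median was 0.92 against 1.92 over 84 genes, below every random list (percentile 0), and 79 of the 84 held a peak. Rpl4 was at 1.30, Rpl8 at 0.01 and Rplp1 at 0.98. With peaks of at least 74 tags alone the list was at 3.27, inside the range of its matches. Translation factors stood at 2.31 against 1.78 (62 genes, percentile 99.2), but the call was lost when random lists were matched on RPKM times exon length (45.5), with the tallest peak (94.5) or among protein-coding genes alone (96.3). Eef1a1 and Eef2, the main elongation factors, were at -1.98 and 0.57 and Eif3g at 2.33.

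By height over RPKM the remaining 10 tested lists lay within the range of their matches. By the share of genes with a peak, histone genes stood above theirs (92.3% against 80.0%, percentile 99.5). So did the respiratory chain (97.4% against 90.6%, 98.9) and proteasome genes (100% against 92.0%, 97.7). Translation factors did as well (100% against 92.9%, 99.6). The matches were not limited to protein-coding genes, of which 96.6% held a peak. The values that follow are heights over RPKM. Cleavage and polyadenylation genes stood at 3.05 against 2.52 (19 genes; Cstf2 3.05, Cpsf1 1.24, Cpsf3 1.68). Histone genes stood at 2.74 against 2.40 (48 of 52 with a peak; Hist1h2af -1.80). Their list also held H3f3b at 1.97 and H1f0 at 2.89, which are replication-independent genes with poly(A) tails. Long non-coding RNAs stood at 2.82 against 2.33 (10 of 12 with a peak; Gas5 3.47, Snhg5 3.22, Malat1 1.08), and the respiratory chain at 1.87 against 1.55 (77 genes; Atp5b 1.03, Atp5k 0.01, Atp5c1 -0.09). Proteasome genes stood at 1.86 against 1.37 (37 genes; Psmd4 2.57, Psmb4 0.78, Psmb1 -0.79), glycolysis at 1.78 against 1.82 (13 genes; Aldoa 1.92, Ldha 1.54, Pkm -0.43) and chaperones at 0.85 against 1.03 (19 genes; Hsp90ab1 0.20, Hspa5 0.12, Cct6a -0.89). Immediate-early genes stood at 2.88 against 2.38 (17 genes; Mcl1 2.38, Myc 0.43, Zfp36l2 0.61) and cell cycle genes at 1.90 against 1.52 (21 genes; Mki67 2.06, Mcm5 2.20, Mcm6 1.73). Markers of other blood cells had 3 genes at RPKM of at least 1 and stood at 2.26 against 1.26 (Pf4 2.55, Itga2b 1.56, Cd79b 2.26). Histone genes moved to percentile 99.99 when matched on RPKM times exon length, while the respiratory chain and the chaperones moved to 0.78 and 0.86. With peaks of at least 74 tags alone the respiratory chain moved the other way, to 99.8, and with the tallest peak to 99.6, where histone genes were at 99.4. Of fibroblast markers 2 reached RPKM 1, Thy1 at 65.3 and Pdgfrb at 2.60, with Col1a1 at 0.873, and they were not tested. Of mitochondrially encoded genes 0 were listed.

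**Figure D5:**
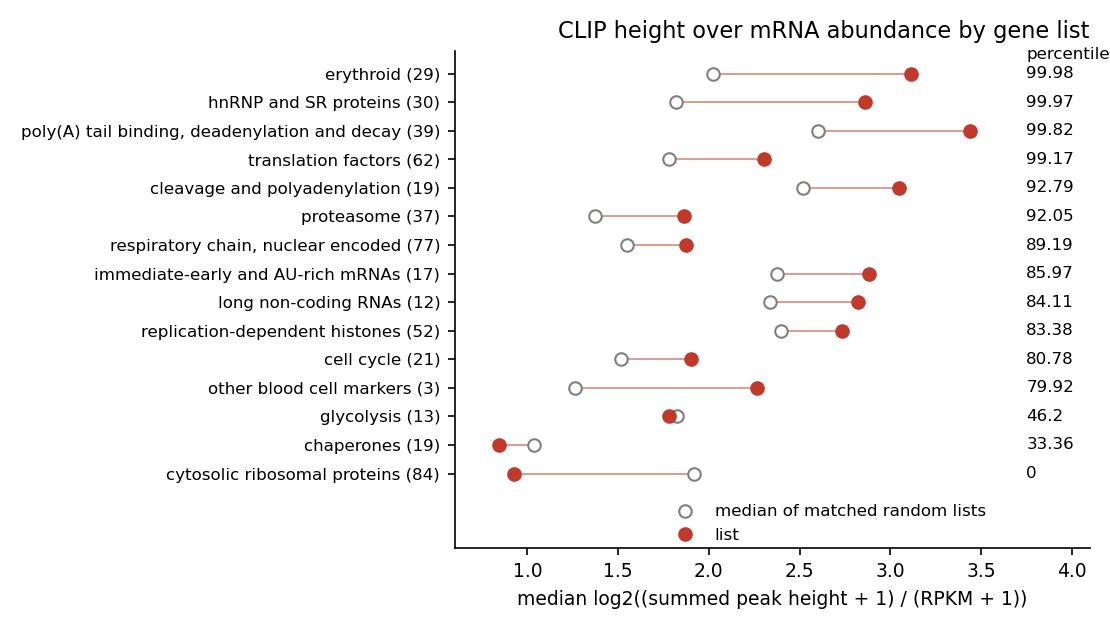
Median log2((summed peak height + 1)/(RPKM + 1)) of each tested gene list (filled) and of its RPKM-matched random lists (open), with the number of genes in parentheses and the percentile among 10000 random lists at the right. Erythroid genes lie at 3.11 against 2.02 and cytosolic ribosomal protein genes at 0.92 against 1.92.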

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

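Of the tests in this part, that of sites covered by at least 5 tags was chosen only after the result was seen.

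A signal lay in data that the comparisons above leave aside: 1357 deletion sites outside annotated genes, of which 657, 48.4% (95% interval 45.7 to 51.1), were deleted in at least 95% of their tags. In 3' UTRs that share was 1.49% (1.24 to 1.76) of 8753 sites, in CDS 2.45% and in introns 44.3% of 521. Sites outside genes had a median coverage of 10 tags against 155 in 3' UTRs. Only 79 of the 1357 lay within 1000 nt downstream of a protein-coding gene, 5.82%, so few lay where a longer 3' UTR would reach. That share was 31.7% for peaks outside genes. Peaks may have been called on annotated genes alone, so the shares of both lists are not compared.

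Low coverage may account for a large part of this pattern: 3' UTR sites weighted to the same coverage were near-complete in 34.4% (32.8 to 36.1) of cases, and listed sites under 5 tags were near-complete in 100% of cases in both regions (383 outside genes and 77 in 3' UTRs). Among sites of at least 5 tags it was not enough, with 8.66% (6.46 to 11.0) of weighted 3' UTR sites against 28.1% (25.3 to 31.1) of 974 sites outside genes. A difference between the genome of this line, or another copy of the sequence, and the reference may contribute. Near-complete exonic sites held AATAAA or AAAAAA less often by a difference of -17.4 percentage points (-23.8 to -9.89; 19.9% of 171 against 37.3% of 9449). AATAAA alone made this difference (7.60% against 29.6%) and AAAAAA did not (13.5% against 11.7%). The groups were not matched on coverage, so this test cannot tell such a difference from low coverage. Of the 130 near-complete sites in 3' UTRs, 77 had under 5 tags, while the median 3' UTR site had 155. Reads placed at the wrong copy may contribute too: near-complete sites were 8.51% (4.48 to 14.4) of 141 sites in pseudogene exons, against 1.61% (1.37 to 1.89) in protein-coding exons. These groups were not matched on coverage either. The design has no control library, so no biological explanation was tested.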

How the results depend on the processing

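The alternatives chosen only after the data were seen are named in the processing text; protein-coding genes alone, joined sites and the rho with RPKM times exon length are among them, and the counts and ranges given here include them all. Over 592 recomputed values of 74 results, 553 counted as unchanged, 9 were weaker, 14 stronger, 6 moved and 10 reversed. Unchanged values kept their side of the threshold, and a change of direction counted as unchanged where neither value lay beyond its threshold. Shares counted as unchanged within their interval, and counts and ranks within a fixed fold. Outside the hexamers and single gene lists the counts were 95 unchanged and 6 moved of 101. The 3' UTR ratio of deletion sites stayed between 2.00 and 2.11 over its settings, and Spearman's rho between 0.283 (number of peaks) and 0.686 (RPKM times exon length). The share of expressed genes with a peak was 79.8% for peaks at or above the median height, 46.8% for the tallest ones of at least 74 tags, 96.6% for protein-coding genes alone and 93.1% at RPKM of at least 5, where fewer peaks or other genes were counted by construction. For the same reason 5' UTR peaks numbered 860 and 86 at the stricter heights. AATAAA at deletion sites in 5' UTRs alone had a log2 ratio of 2.32 with an interval that reached 0, on 72 sites.

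Of the hexamers, the reversals were changes of sign with a value apart from 0 before or after. TTTTTT at deletion sites changed sign in this way with windows of 10 nt (-0.31), and GCAGGG in 5' UTRs alone (0.51). At sites with at least the median number of deletions TTTTTT (-0.09) and GTTTGT (-0.05) also fell below 0. Their intervals included 0, so they counted as unchanged. Against an any-exon background TTTTTT, GTTTGT and TGTTTG at deletion sites passed above 0 (0.80, 0.68 and 0.57), as did TTTTTT (0.40) and TGTTTG (0.24) with windows of 50 nt, and TTTTTT (0.19) with sites within 10 nt joined. In peaks TTTTTT changed sign for the tallest peaks (0.10) and with windows of 50 nt (0.17), GTTTGT with an any-exon background (0.19) and windows of 50 nt (0.0933), and TGTTTG with that background (0.0798) and those windows (0.0515). Against that background TTTTTT in peaks was no longer apart from 0 (-0.04). Matching on RPKM times exon length moved translation factors to percentile 45.5 and the respiratory chain to 0.78, on the other side of the middle. The respiratory chain was at 99.8 with the tallest peaks alone, so its place depends on the setting in both directions. For the changes of hexamers and lists the cause was not tested.

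No paired analysis was possible because the CLIP-seq and mRNA-seq samples, which share replicate numbers 1 and 2, were each represented by pooled values. Leaving out a CLIP-seq replicate or an mRNA-seq replicate was not run for the same reason. Depth limits the weak end: 2570 genes lay at RPKM 1 to 5, where the median summed height was 8 tags, so a gene without a peak there cannot be called unbound.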

Other observations

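Of the tests in this part, those of reads running into the tail, of errors in runs of a single base and of gene length were chosen only after the result was seen, as were the comparison of sites near and far from ends and the positions of hexamers.

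ATATAA and AATAAA differed in where they occurred within 3' UTRs. ATATAA lay in the window of 15.3% of 4654 sites farther than 100 nt from an annotated end and of 9.03% of 3589 sites nearer to it. AATAAA went the other way, with 49.9% near and 17.7% far, where positions drawn from the same zones held it in 22.0% and 3.41% of windows. Drawn windows of the near zone, which is 100 nt long, often cover the same hexamer as the sites, so the enrichments of both zones are not compared. AAAAAA lay in 10.1% of near and 13.6% of far windows. ATATAA started at the deleted base in 3.01% of 8564 sites and, nearly as often, 1 nt (2.84%), 3 nt (2.93%) and 4 nt (2.95%) upstream of it, but 2 nt upstream in 0.0117%. AATAAA started most often 1 nt upstream of the deletion (3.94% against 0.125% of drawn positions). AAAAAA had no single placement, with 3.25% and 3.23% at 1 and 2 nt downstream and 2.39% at 5 nt upstream, but with the deletion inside the run, at 2 nt upstream, it stood at 0.210% against 0.248%. TTTTTT was likewise placed by its ends, starting at the deleted base in 0.619% of sites against 0.348%, and 5 nt upstream in 0.537% against 0.308%, but 2 nt upstream in 0.0234%. Within a repeated sequence the alignment alone sets which base is called deleted.

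The enrichment of hexamers rich in A and T at deletion sites was weighed against 3 technical explanations. Reads running into the tail would leave no AATAAA away from annotated ends. Beyond 100 nt its log2 ratio was 1.92 (1.79 to 2.04). That value counted all sites outside 3' UTRs as beyond 100 nt and drew positions from whole regions. For 3' UTR sites beyond 100 nt, against positions drawn from the same zone, it was 2.38 (2.24 to 2.52). Unannotated ends stay open. Errors in runs of a single base would raise TTTTTT as they raise AAAAAA, yet TTTTTT stood at 0.0108 and AAAAAA at 1.99, and against an any-exon background at 0.80 and 2.51; errors in repeats of more than a single base, such as AT, were not tested. Base content without order, if even over the window, would give all hexamers of 5 A and 1 T the same ratio. AATAAA exceeded the median of the other 5 by 0.35 (0.25 to 0.46), although AAATAA was as high, at 2.47 against 2.42. Base shares changed with position, with T at 48.6% at the deleted base and A at 50.5% 4 nt downstream. So the test cannot exclude base content that varies by position. A sequence preference of the protein is a hypothesis that may account for the pattern, but ultraviolet cross-linking has base preferences of its own, and without a CLIP-seq control no biological explanation was tested.

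The low CLIP height of ribosomal protein genes was weighed in the same way. Short genes, for which RPKM is divided by length and height is not, stay open as an explanation. Matched on RPKM times exon length, the list stayed at percentile 0. That matching changed the random lists and not the ratio itself. The ratio would stay low for short genes, so the test cannot exclude gene length. Loose matching of abundant genes would be cured by 100 bins of RPKM, and the list was then at percentile 0.45. Reads shared with processed pseudogenes remain open: across the 84 genes, of which 62 have a pseudogene named after them, rho between the number of such pseudogenes and the log2 ratio was 0.0810 (-0.154 to 0.302), an interval that includes 0. No biological explanation was tested.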
